A study of Homo sapiens with 4 samples.

How the data were processed

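Mature miRNA was measured by quantitative PCR in 4 RNA samples of U2OS, a human osteosarcoma line, with 1 sample per group. Per the labels, a pair of samples came from cells infected with lentivirus carrying a control short hairpin RNA (shNS) or one against DDX1 (shDDX1) and selected with puromycin. The other pair came from untreated cells and cells treated with neocarzinostatin (NCS), an enediyne that cuts both DNA strands, at 500 ng/ml for 6 h. Total RNA was extracted with Trizol, reverse transcribed with an Exiqon kit and measured with SYBR Green on a human 2-panel, 384-well plate set, per the labels. The instrument, its threshold and its baseline settings were not given in the sources used here.

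The authors deposited 3 tables. The first gives the quantification cycle (Ct) of each of 768 wells per sample, 384 on panel I and 384 on panel II, or marks the well as undetermined. The second gives shifted Ct values. Set against the first table, the shNS and shDDX1 values were moved by -0.789 cycles on panel I and 0.789 on panel II, in both samples alike. That is the distance between the mean Ct of the inter-plate calibrator wells on the panels divided by 2, so a plate-to-plate difference between shNS and shDDX1 stayed in the values. In the NCS pair the shift differed from well to well, and numbers stood for wells that were undetermined in the first table. How those were made was not given in the sources used here. The third table is a linear fold of each sample over its control as deposited by the authors, and it matched 2 to the power of the difference in shifted Ct within 0.01 on the log2 scale for 99.7% of assays in the knockdown pair and 99.6% in the NCS pair. No further centring had been applied. In the authors' deposited fold table, 22 miRNAs with a missing shifted Ct in untreated cells carry folds between 3.87e-13 and 8.6e-06, as if the missing value were 0, and these were not used. A further 2 columns of that table, for the control samples, were not used.

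The Ct table was the starting point here. The level of an assay was minus its Ct, centred in each sample on the mean Ct over the 67.4% of 740 miRNA wells with Ct under 35 in all 4 samples. A log2 ratio was the difference of centred levels, with 1 cycle taken as 1 doubling. An assay counted as quantified where Ct was under 35 in both samples of a comparison, and as higher or lower at 2-fold. Of 740 miRNA wells, 737 different assays remained after miR-103, miR-191 and miR-423-5p, present on both panels, were averaged. Blank wells, spike-ins, small nuclear and nucleolar RNAs and assays with bracketed names were left out of the counts.

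With 1 sample per group there is no replicate check, and no p-value or standard error was computed. Technical spread was taken from wells repeated within or across plates. The 3 calibrator wells of a plate had a pooled SD of 0.191 cycles. From 7 assays present on both panels, the SD of an uncentred log2 ratio was 0.38 for the knockdown and 0.79 for NCS. Centring each panel first raised these SDs to 0.57 and 1.06, and the smaller ones were used to judge whether a value moved between settings. The 0.79 for NCS rests largely on miR-423-5p, whose panels differed by 2.71. The next largest difference was -0.84, for the spike-in UniSp6.

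The comparisons, the 19 miRNA lists and the naming rule were fixed before the data were examined. The rule named, per comparison, the 10 quantified miRNAs with the largest fall and the 10 with the largest rise, all members of the miR-200 and p53 target lists, the reference assays, the lowest and highest member of every other list, and any miRNA with Ct under 32 in one sample and none under 35 in the other, given as a bound. For the overlap it named the 10 with the largest smaller change. A list was described by its median and by the percentile of that median among 10000 random lists of the same size, each member drawn from the 50 assays nearest in mean level. Overlaps were set beside the product of the list sizes divided by the number of miRNAs quantified in both comparisons.

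Alternatives fixed beforehand were median centring, small RNA references, reference miRNAs, no centring, centring per panel, the authors' deposited tables, limits of Ct 37, Ct 32 or none, thresholds of 1.5-fold and 4-fold, guide arms only, and unmatched random lists. Added after the data were seen were calibration of each plate to its 3 calibrator wells, subtraction of the median of wells within 2 rows and 2 columns, each panel alone, removal of miRNAs with a Ct under 12 in any sample, lists matched also on panel and on middle or outer columns, and outer columns alone. A panel taken alone was centred on its own wells. The middle of a plate, columns 7 to 18, was defined after the data were seen. Hairpins were paired by assay name, and 486 of 524 hairpin names matched a miRNA gene of the RefSeq table for GRCh38.p14, used only for which genes neighbour each other within 10 kb. Intervals are percentile intervals from 2000 bootstrap draws of miRNAs, at 95%, and describe these samples only.

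The ratio and counting steps were tested on simulated data built from the real Ct values with 200 assays changed 2 cycles. On 726 assays of the knockdown pair and 528 of the NCS pair, 100% of the changed assays were recovered in each and 0 unchanged assays were called. With a plate shift of 0.9 cycles added to panel I, 13 of 518 unchanged assays of the knockdown pair and 3 of 297 of the NCS pair were called under the common centring, against 0 when centred per panel. The simulated noise was smaller than the spread of the duplicated assays, and no effect of well position was built in. The simulation therefore checks the computation and gives no rate of false calls for the real data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.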

Results

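Mature miRNAs were measured in U2OS osteosarcoma cells in 4 samples that form 2 comparisons with no sample in common. The first asks which miRNAs depend on DDX1, a DEAD-box RNA helicase, and the second which miRNAs move after DNA double-strand breaks made by neocarzinostatin (NCS). Each group had 1 sample, so no difference below has a replicate check. Ct under 35 was reached in 732 of 740 miRNA wells in shNS, 723 in shDDX1, 521 in untreated cells and 591 in NCS-treated cells. The mean Ct over the 67.4% of wells under 35 in all 4 samples was 25.8 in shNS, 26.1 in shDDX1, 30.1 in untreated and 29.4 in NCS-treated cells, so ratios were taken only within a pair. DDX1 mRNA was not measured on these panels, and the extent of its knockdown is not analysed here.

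In shDDX1 cells, the guide strands of all 5 miR-200 family members were at least 2-fold lower than in shNS cells. This family represses the ZEB transcription factors and maintains epithelial character. miR-200b was 6.21-fold lower, miR-200a 5.04-fold, miR-141 2.81-fold, miR-429 2.34-fold and miR-200c 2.33-fold. These guide strands read Ct 27.1 to 30.8 in shNS and 29.4 to 32.4 in shDDX1. The earliest blank (water) well read 26.6 and 26.5, and one on panel I 27.8 and 27.3, so a share of background signal was not excluded. Of the opposite arms, miR-200b* was 3.63-fold lower, whereas miR-141* was 2.54-fold and miR-200c* 2.04-fold higher and miR-200a* had a log2 ratio of 0.25. Over the 9 assays, 6 were lower and 2 higher, with a median log2 ratio of -1.23 at percentile 0.59 of level-matched random lists. The study is known to have followed this family, so the list is not independent evidence. The 5 guide strands were below 0 in each of 7 scalings, while miR-200c and miR-429 missed 2-fold in 2 of them, miR-141* and miR-200c* passed it in 3 and 1, and miR-200a* changed sign between scalings. With each panel centred separately 4 assays were lower and 0 higher at percentile 4.05, and among panel I assays alone the percentile was 12.5. The guide strands lie on panel I and the opposite arms on panel II, and the panels differed as a whole in this comparison.

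miRNAs of the imprinted cluster at 14q32 were also lower in shDDX1. Of 57 quantified assays, 25 were at least 2-fold lower and 5 higher, and the median log2 ratio of -0.79 lay at percentile 0 of matched random lists. miR-329 was 29.2-fold lower, miR-369-5p 20.5-fold and miR-409-3p 15.3-fold, while miR-431* was 6.12-fold higher. With each panel centred separately 23 assays were lower and 3 higher, with a median of -0.63. In the miR-30 family 4 of 11 assays were lower and 0 higher, led by miR-30b* at 3.16-fold lower, with a median of -0.74. Centred per panel 1 was lower, and after subtraction of neighbouring wells 1 was lower and the median was -0.0087. In the let-7 family, 4 of 18 assays were lower and 1 higher, from let-7f at a log2 ratio of -2.57 to let-7i* at 1.18. Centring per panel left 4 lower and 0 higher, with let-7i* at 0.74, and subtraction of neighbouring wells 3 lower and 0 higher. Among p53 transcriptional targets, miR-34a was 3.83-fold lower, miR-194* 2.18-fold and miR-34a* 2.09-fold higher, and the other 10 of 13 were within 2-fold. Of these, miR-194* and miR-34a* were within 2-fold when each panel was centred separately, at log2 ratios of 0.69 and 0.63, and miR-34a was at -0.53 after subtraction of neighbouring wells.

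Over all 716 quantified miRNAs, 17.3% were at least 2-fold lower and 11%, or 79 miRNAs, at least 2-fold higher in shDDX1. When each panel was centred separately, 89 of the lower and 38 of the 79 higher kept the call. The deepest falls were those of miR-875-5p, miR-548c-3p and miR-570, with log2 ratios of -19.48, -16.55 and -14.93. These rest on shNS Ct values of 7.61, 14.9 and 8.45. Apart from the 14q32 members named above, miR-17* followed at -8.80, miR-572 at -7.59, miR-877* at -4.68 and miR-488 at -4.35. On panel I, miR-570, miR-572, miR-488 and miR-548c-3p share a plate column, in wells D16, H16, I16 and J16. A fault of those wells was not tested. The highest ratios were 5.87 for miR-579, 5.30 for miR-592, 3.79 for miR-663b, 3.27 for miR-603, 3.09 for miR-339-3p, 3.01 for miR-1184, 3.0 for miR-513a-5p, 2.61 for miR-431*, 2.53 for miR-93* and 2.46 for miR-1911. That of miR-603 rests on Ct values of 10.3 in shNS and 7.33 in shDDX1. Whether such early readings are errors of the instrument or plate is not known, and amplification curves are not analysed here. As bounds, miR-513c was at least 6754-fold lower, miR-617 at least 129.6-fold, miR-1266 at least 67.4-fold, miR-325 at least 14.9-fold and miR-620 at least 9.03-fold lower, while miR-371-3p was at least 127.8-fold and miR-802 at least 76.1-fold higher. The reference assays had mean log2 ratios of 1.0 for U6, 0.54 for SNORD38B, 0.45 for SNORD49A, 0.45 for miR-103, 0.37 for miR-191 and 0.57 for miR-423-5p.

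Of the lower miRNAs 85.5% were on panel I, and of the 79 higher ones 69 were on panel II. In the middle columns of panel I, 7 to 18, 76 of 185 miRNAs were lower, with a median of -0.82, and in the outer ones 30 of 178, with a median of -0.24. Lower miRNAs made up 61.1% of those past 2-fold, against 91.5% with the small RNAs as reference, 86.8% with the reference miRNAs, 80.7% without centring and 72.6% with each plate set to its calibrators. Against the common centring, the median ratio was shifted by -0.67, -0.46 and -0.30 with these first 3 references, and by -0.10 under median centring.

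Of the p53 transcriptional targets, miR-34c-5p was 12.5-fold higher after NCS, miR-34b 3.75-fold and miR-34b* 2.74-fold, each at least 2-fold higher in all 7 scalings. Their Ct in untreated cells was 33.9, 34.6 and 33.3, close to the limit of 35. miR-34a went from a Ct of 35.8 to 23.6, at least 1592-fold higher, or 912-fold with each panel centred separately. Its well lies in the middle columns of panel I, where untreated cells read 0.917 cycles later than in the outer ones relative to shNS. The median Ct difference from shNS in those columns was 5.08 cycles in untreated and 3.02 in NCS-treated cells. miR-34a read Ct 22.2 in shDDX1 and earlier still in shNS, so the late reading was that of untreated cells. Loss of signal in untreated cells was not excluded for miR-34a. Its opposite arm miR-34a* had a log2 ratio of -0.14 and miR-34c-3p one of 0.51, both of which changed sign between scalings. miR-192 was 2.15-fold higher, and miR-192* and miR-194* were 2.17-fold and 2.29-fold lower. Centring per panel left these 1.23-fold higher and 1.22-fold and 1.29-fold lower, and after subtraction of neighbouring wells miR-192 and miR-192* changed sign. miR-107, miR-194, miR-215 and miR-605 were within 2-fold, at log2 ratios of 0.46, 0.17, 0.19 and -0.18, and each changed sign between scalings. After subtraction of neighbouring wells miR-107 was at -1.35. Over the 12 quantified assays of the p53 target list 4 were higher and 2 lower, and the median of 0.32 lay at percentile 93.3 of matched random lists. Centred per panel, 3 were higher and 0 lower, with a median of 0.0064 at percentile 69. The median was 1.11 against small RNAs and 1.05 without centring, settings that shift all assays alike.

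The 5 miR-200 guide strands were higher after NCS. miR-200b was 5.62-fold higher, miR-429 3.11-fold, miR-200a 3.07-fold, miR-200c 2.98-fold and miR-141 2.24-fold. miR-200b* was 3.19-fold lower, and miR-141* and miR-200a* had log2 ratios of 0.14 and -0.80. Of 8 quantified assays, 5 were higher and 1 lower, with a median of 1.37 at percentile 99.9. With each panel centred separately, only miR-200b of the 8 stayed at least 2-fold higher, 0 were lower, with miR-200b* at 1.8-fold lower, and the median was 0.79, at percentile 96.8. After subtraction of neighbouring wells miR-200a was at 0.75 and miR-200b* at -0.87. In untreated cells the Ct of miR-200a, miR-200b and miR-429 was 34.9, 34.3 and 34.7, close to the limit of 35.

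**Figure D1:**
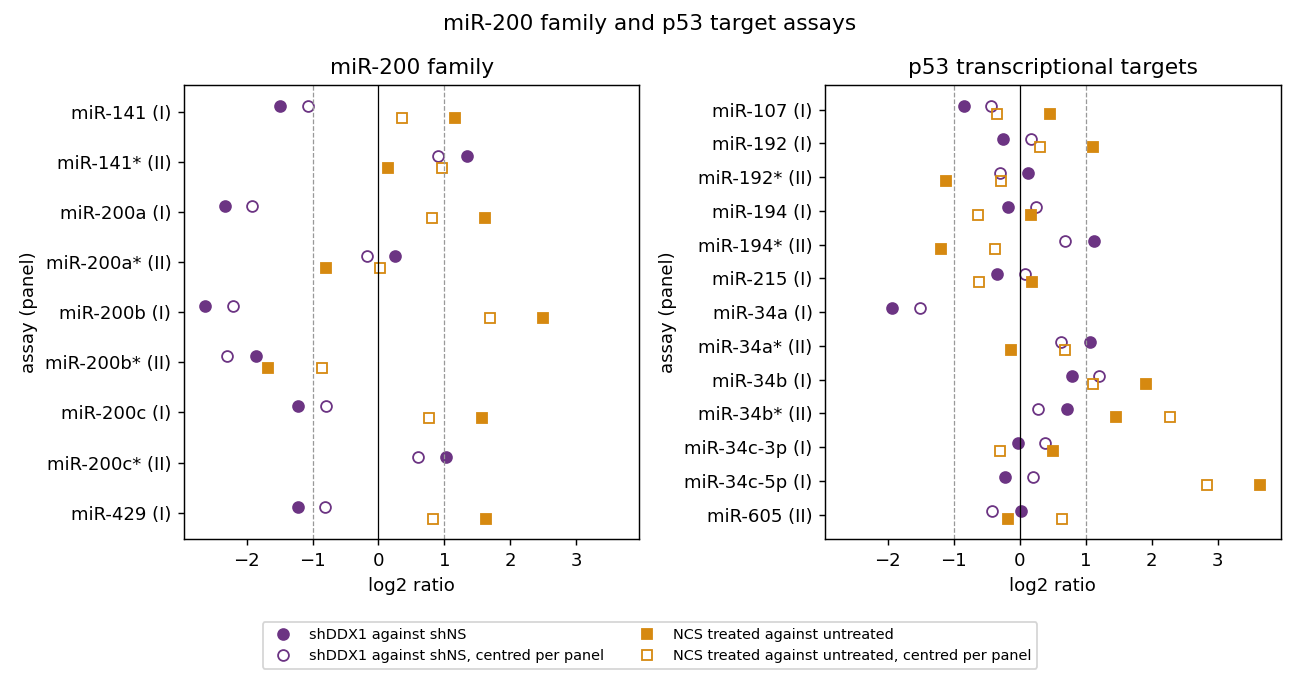
log2 ratios of the miR-200 family (left) and p53 transcriptional target assays (right), with the panel in brackets. Circles are shDDX1 against shNS and squares NCS treated against untreated, 1 sample per group and no error bars, filled for the common centring and open for centring per panel, and dashed lines mark 2-fold.

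Over all 498 miRNAs quantified in both NCS samples, 84 were at least 2-fold higher and 111 at least 2-fold lower. When each panel was centred separately, 53 of the 84 and 30 of the 111 kept the call. The highest log2 ratios were 17.34 for miR-570, 8.33 for miR-186, 7.71 for let-7a, 6.72 for miR-101, 6.12 for miR-339-5p, 6.01 for miR-425, 6.00 for miR-155, 5.87 for miR-96, 5.19 for miR-1979 and 5.17 for miR-199a-5p. That of miR-570 rests on Ct values of 33.4 in untreated and 15.3 in NCS-treated cells, and it is open to the same doubt as the early readings in shNS. These 10 are all panel I assays in the middle columns. After subtraction of neighbouring wells all 10 stayed at least 2-fold higher, the smallest at 3.02. Among them, miR-186 read Ct 21.7 in shNS, 34.3 in untreated and 25.3 in NCS-treated cells. Loss of signal in untreated cells was not excluded for these 10 rises. The lowest log2 ratios were -5.13 for miR-579, -2.93 for miR-525-3p, -2.67 for miR-15a*, -2.59 for miR-520d-3p, -2.54 for miR-2113, -2.41 for miR-365*, -2.31 for miR-661, -2.26 for miR-636, -2.20 for miR-23b* and -2.19 for miR-148b*. These 10 are all panel II assays and lead under the common centring. When each panel was centred separately all 10 stayed at least 2-fold lower but 1 was still among the 10 lowest, and miR-100, on panel I, was at -2.67. A further 22 miRNAs, all on panel I, were read under Ct 32 after NCS and not under 35 before, among them let-7f at least 650.02-fold, miR-572 at least 638.9-fold and let-7i at least 227.6-fold higher. Of the 22, 20 lie in the middle columns, and with each panel centred separately these 3 bounds were 372-fold, 366-fold and 130.4-fold. let-7f read Ct 21.6 in shNS, 35.6 in untreated and 24.9 in NCS-treated cells, and let-7i 22.8, undetermined and 26.4. Loss of signal in untreated cells was not excluded for these either. On panel II, miR-412, miR-146b-3p and miR-7-2* were at least 19.5-fold, 18.6-fold and 16-fold lower, or between 9.01-fold and 11-fold with each panel centred separately. Reference assays stood at -0.55 for U6, -0.97 for SNORD38B, -0.85 for SNORD49A, -0.77 for miR-103, -0.88 for miR-191 and 0.65 for miR-423-5p. The last averages wells that disagreed, with uncentred log2 ratios of 2.74 on panel I and 0.029 on panel II. For miR-103 these were -0.034 and -0.037, and for miR-191 -0.040 and -0.26. The reference miRNA scaling includes miR-423-5p.

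Of the 84 higher miRNAs 76 were on panel I, 63 of them in the middle columns 7 to 18, and 99 of the 111 lower ones were on panel II. The panel I median was 1.21 in the middle columns and -0.15 in the outer ones, against -0.96 and -0.72 on panel II. Higher miRNAs made up 43.1% of those past 2-fold, against 86.3% with the small RNAs as reference, 61.1% with the reference miRNAs, 83.2% without centring and 70.2% with each plate set to its calibrators. The median ratio was shifted by 0.79, 0.33 and 0.73 with these first 3 references.

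**Figure D2:**
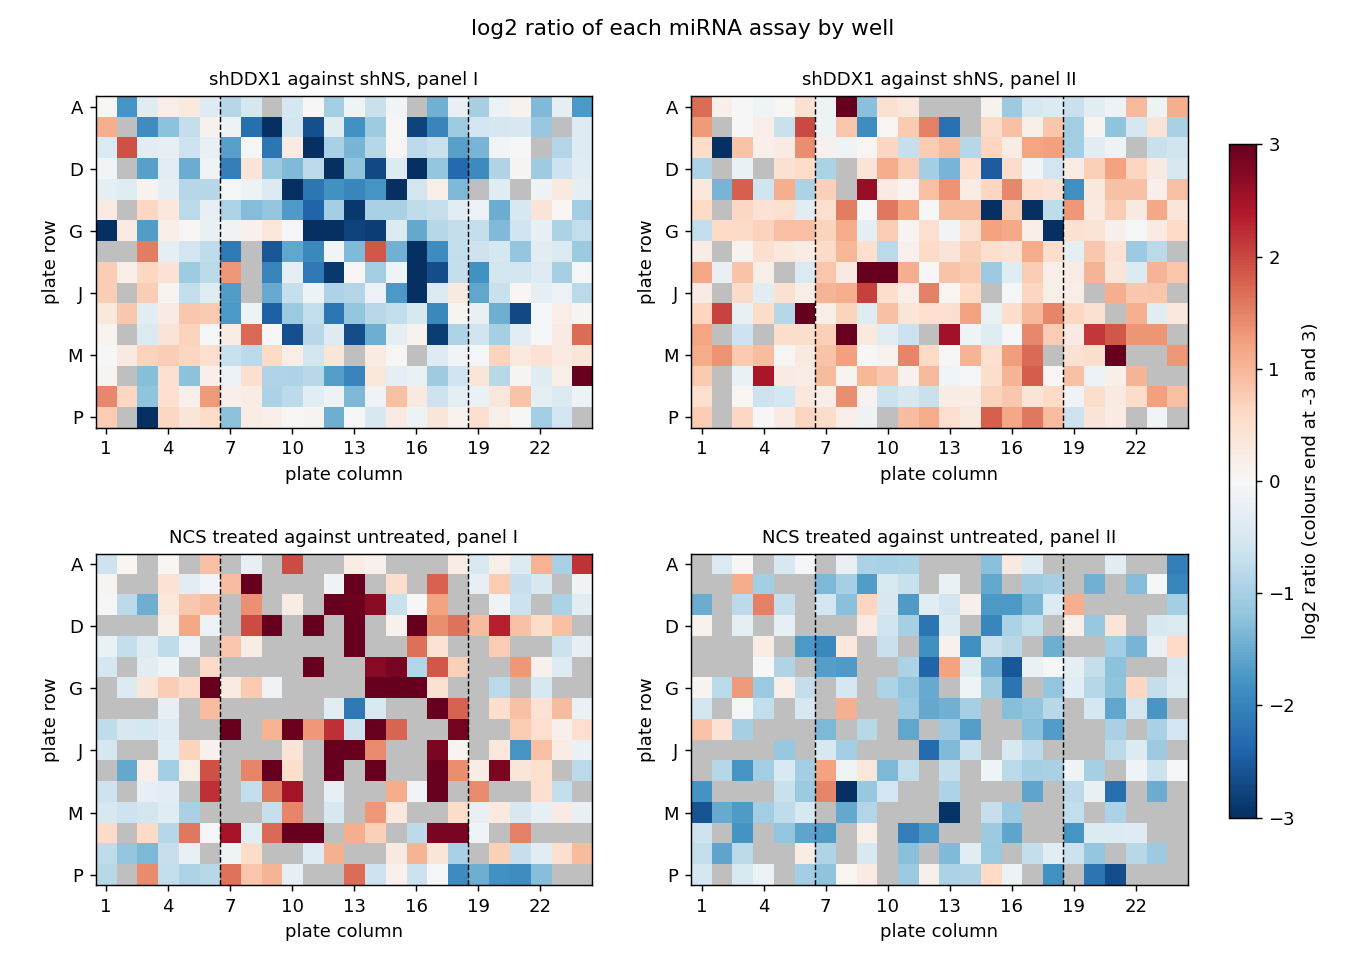
log2 ratio of each miRNA assay at its plate row and column, for shDDX1 against shNS (top) and NCS treated against untreated (bottom) on panel I (left) and panel II (right). Grey wells hold no quantified single-panel miRNA assay, and dashed lines bound columns 7 to 18, where the panel I medians were -0.82 for shDDX1 and 1.21 for NCS.

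The miRNAs lower in shDDX1 were set against those higher after NCS. Of the miRNAs quantified in both comparisons, 67.3% of all assays, 33 were at least 2-fold lower in shDDX1 and at least 2-fold higher after NCS, where independent lists would share 10.2. There were 21 miRNAs higher in shDDX1 and lower after NCS, with 11.5 for independent lists. A further 8 were lower in both, with 13.3 for independent lists, and 1 was higher in both, with 8.81. Taken within panels, the 21 were all on panel II, with 18.6 for independent lists. Lower in both were 3 on panel I, with 2.3, and 5 on panel II, with 4.84. Higher in both were 1 on panel I, with 1.82, and 0 on panel II, with 1.51. By the smaller of their changes the leading members were miR-570, miR-18a*, miR-186, miR-200b, miR-376a, miR-16, miR-128, miR-26b, miR-449a and miR-339-5p. The place of miR-570 rests on the early Ct values of 8.45 in shNS and 15.3 in NCS-treated cells, which may be errors. miR-18a* had log2 ratios of -2.84 and 5.03, miR-376a -2.44 and 3.59, miR-16 -2.41 and 4.98, miR-128 -2.26 and 3.42, miR-26b -2.89 and 2.20, and miR-449a -2.17 and 4.47. After subtraction of neighbouring wells miR-16 was at -0.78 and miR-339-5p at -0.15 in shDDX1 and miR-26b at 0.78 after NCS, and 16 of the 33 kept both calls. All 5 miR-200 guide strands were among the 33, but only miR-200b kept both calls when each panel was centred separately.

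Across miRNAs, which are not independent replicates, the 2 ratios had a Spearman correlation of -0.499 and a Pearson correlation of -0.582. Of the 33 miRNAs 32 were on panel I, and 26 of those lay in its middle columns. Within panel I the overlap was 32 against 14.6 for independent lists, and within panel II 1 against 0.395. The Spearman correlation was -0.524 on panel I and -0.132 on panel II. With each panel centred separately 19 miRNAs overlapped, 17 of them among the 33, against 6.75 for independent lists. Under that centring 19 others were higher in shDDX1 and lower after NCS, against 7.61, and 3 were lower in both, against 10.3.

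**Figure D3:**
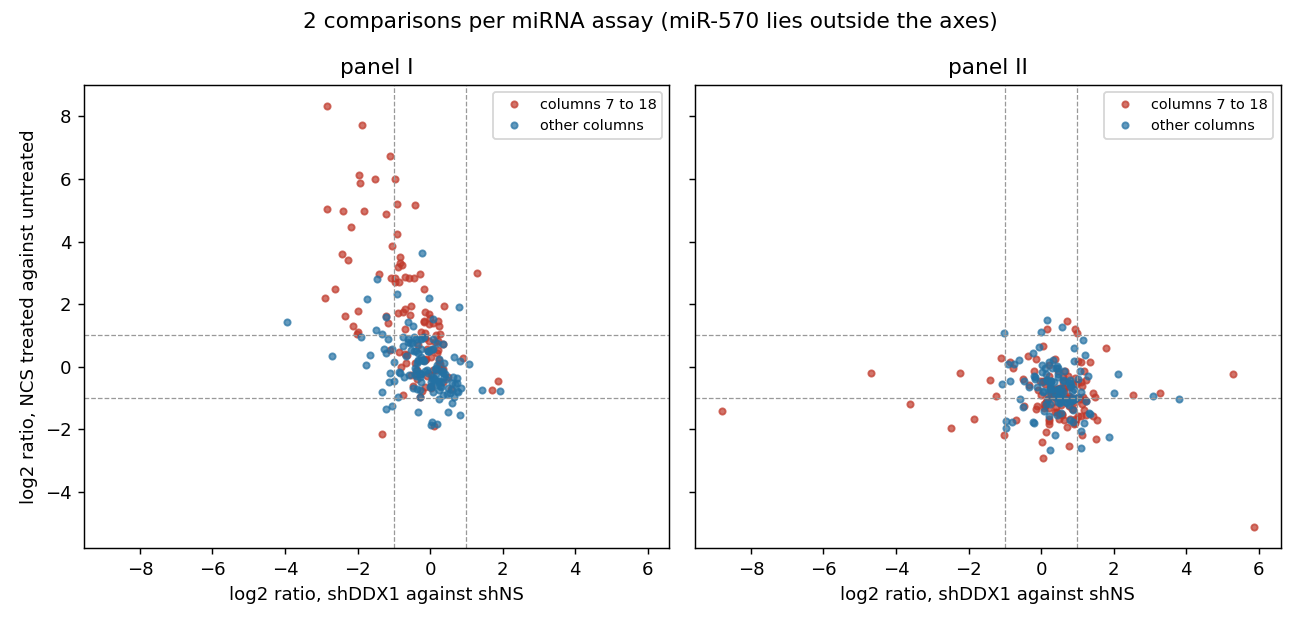
log2 ratio of each miRNA in shDDX1 against shNS (x axis) and NCS treated against untreated (y axis), for panel I (left) and panel II (right), with plate columns 7 to 18 in red, other columns in blue and dashed lines at 2-fold. Spearman correlations were -0.524 on panel I and -0.132 on panel II.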

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

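The water wells were looked at because they lie outside the main measurement. Of 9 wells named as blanks per sample, 6 gave a Ct in shNS and 7 in shDDX1, while 0 did in untreated or NCS-treated cells. The earliest Ct of a water well was 26.6 in shNS and 26.5 in shDDX1, in the same panel II well. A panel I water well read 27.8 and 27.3, and the earliest of the others read 34.6 and 34.8. Of miRNA wells with a Ct, 61% in shNS and 65.4% in shDDX1 read later than the earliest water well. No explanation was tested.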

How the results depend on the processing

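Calibration per plate, subtraction of neighbouring wells, single panels, removal of very early wells and outer columns alone were chosen after the data were seen. No paired analysis was possible because each group has 1 sample. Median centring, a limit of Ct 37 and removal of miRNAs under Ct 12 kept all 5 counts within 1.5 times. Shares of quantified miRNAs are given in the order lower in shDDX1, higher in shDDX1, higher after NCS, lower after NCS and overlap, beside 17.3%, 11%, 16.9%, 22.3% and 6.65%. Against small RNAs they were 35.9%, 3.35%, 31.7%, 5.02% and 16.9%, and against reference miRNAs 29.3%, 4.47%, 21.5%, 13.7% and 11.9%. Without centring they were 24.6%, 5.87%, 28.9%, 5.82% and 11.7%. The authors' deposited normalized table and fold table each gave 5.87% higher in shDDX1, 31.3% higher and 6.43% lower after NCS and an overlap of 12.1%. Under Ct 32, 12.7% were higher and 18.4% lower after NCS and 3.19% overlapped. With no limit 22.2% were higher after NCS and 8.86% overlapped. At 1.5-fold 27.9% were lower and 23.3% higher in shDDX1, 40.6% lower after NCS and 11.5% overlapped. At 4-fold the 5 shares were 6.01%, 1.82%, 8.23%, 2.81% and 1.81%. Centring per panel left an overlap of 3.83%. The other 4 counts stayed within 1.5 times but with other members, since 89 of those lower and 38 of 79 higher in shDDX1, and 53 of 84 higher and 30 of 111 lower after NCS, kept the call. After neighbour subtraction 72, 39, 57 and 32 did, and with plate calibration 91, 31, 80 and 35. Plate calibration left 6.28% higher in shDDX1 and 7.83% lower after NCS. Neighbour subtraction left 12.7% lower after NCS and an overlap of 4.05%. Panel I alone, centred on its own wells, gave 19.6%, 7.71%, 18%, 33.6% and 6.4%. Panel II alone, likewise centred, gave 11.7%, 8%, 9.39%, 7.35% and 1.23%. Under the common centring these shares were 29.2%, 2.75%, 30.4%, 4.8% and 12.8% on panel I. On panel II they were 5.14%, 19.7%, 3.27%, 40.4% and 0.41%. Fewer assays enter with a single panel or a stricter limit, and a single panel was also centred anew. Otherwise the cause was not tested.

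The rank correlation of -0.499 was -0.375 when centred per panel, -0.316 calibrated, -0.283 after neighbour subtraction, -0.132 on panel II alone and -0.626 under Ct 32. The miR-200 median in shDDX1, -1.23, was -1.89 against small RNAs, -1.69 against reference miRNAs, -0.80 centred per panel and -0.17 in the authors' deposited normalized table, where miR-200c and miR-200b* were moved by a further 2 cycles in shDDX1. On panel II alone, which holds only opposite arms, it was 0.21 with that panel centred on its own wells, and after NCS 0.030. Under the common centring the opposite arms had medians of 0.64 and -0.80. The p53 target median in shDDX1 was -0.70 against small RNAs and -0.50 against reference miRNAs. The percentiles of the p53 target list stayed between 2.5 and 97.5 under all alternatives run, and those of the miR-200 list stayed outside this range under both other matchings. The miR-200 percentile in shDDX1, 0.59, was 4.05 centred per panel, 4.73 calibrated, 62.3 and 7.15 in the authors' deposited normalized and fold tables, 12.5 on panel I and 85 on panel II. After NCS, 99.9, it was 96.8 centred per panel, 92.2 in both of the authors' deposited tables, 91.5 on panel I and 41.9 on panel II. Among the miRNAs picked by the naming rule and at least 2-fold from control, the sign changed in 5 combinations of a value and an alternative. Values within 2-fold and miRNAs outside the rule were not counted in this. miR-200c in shDDX1 was 0.47 in the authors' deposited normalized table. After NCS, miR-513c was 0.24 in both of the authors' deposited tables, and miR-192 was -0.31 and miR-192* 0.22 after neighbour subtraction. The causes were not tested. Of the other such combinations, for single miRNAs and further lists, 2295 moved by less than the duplicate-well SD, or for a percentile kept its side of 2.5 and 97.5, and 679 did not. For NCS that SD rests largely on miR-423-5p, so fewer values count as moved. In untreated cells 98 miRNA wells were undetermined, which limits what can be quantified in the NCS pair.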

Other observations

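The plate calibrator tests and the division into middle and outer columns were chosen only after the result was seen. Of muscle markers in shDDX1 2 of 8 were lower and 1 higher, from miR-499-5p at -1.71 to miR-499-3p at 1.69, and after NCS only miR-133a was quantified, at 0.90. Of blood cell markers 2 of 10 were lower and 2 higher in shDDX1, from miR-142-3p at -1.07 to miR-223* at 1.69. After NCS 2 of 5 were lower and 1 higher, from miR-451 at -1.83 to miR-142-3p at 2.84. Of neuron and liver markers 3 of 9 were lower in shDDX1, from miR-128 at -2.26 to miR-9* at 0.16, and after NCS 2 of 7 were higher and 1 lower, from miR-122 at -1.36 to miR-128 at 3.42. Of mesenchymal and bone-lineage markers 0 of 15 were lower and 2 higher in shDDX1, from miR-199b-5p at -0.99 to miR-10a* at 1.58, and after NCS 3 of 11 were higher and 1 lower, from miR-214* at -1.12 to miR-199a-5p at 5.17. Centred per panel, miR-142-3p in shDDX1 and miR-214* after NCS were within 2-fold, and after neighbour subtraction so were miR-499-5p in shDDX1 and miR-122 after NCS.

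The other lists are given with the shDDX1 median first and the NCS median second. Drosha-independent miRNAs, which bypass the nuclear cleavage step, had a median of 0.54 in shDDX1, with 3 of 9 higher and 2 lower, from miR-877* at -4.68 to miR-1236 at 1.23, and of -0.49 after NCS, with 3 of 8 lower, from miR-1236 at -1.55 to miR-320a at 0.79. Centred per panel, 1 was lower and 0 higher in each comparison, and after neighbour subtraction 1 and 0 were lower and 0 higher. miRNAs whose processing p53 promotes had medians of -0.38 in shDDX1, with 2 of 7 lower and 1 higher, from miR-16 at -2.41 to miR-16-2* at 1.48, and 0.88 after NCS, with 2 of 5 higher and 0 lower. Centred per panel these medians were 0.045 and 0.078, the latter with 1 lower and 1 higher, and after neighbour subtraction 0 of 7 passed 2-fold in shDDX1. The miR-15/16 family stood at -0.25 and -0.53, with 3 of 12 lower and 2 higher in shDDX1, and 1 of 10 lower and 2 higher after NCS. Clusters around miR-17-92 stood at -0.03 and -0.69, the latter with 5 of 20 lower and 4 higher, from miR-106a* at -1.96 to miR-18a* at 5.03. After NCS, centring per panel gave 6 lower and 1 higher, and neighbour subtraction 4 lower and 1 higher with a median of -0.25. The miR-29 family stood at 0.40 and -0.09, with miR-29b at 1.86 in shDDX1, and from miR-29a* at -1.05 to miR-29b-2* at 2.84 after NCS. The miR-23/27/24 clusters stood at 0.25 and -0.43, with 1 of 10 lower and 2 higher in shDDX1, from miR-27b at -1.05 to miR-23b* at 1.14, and 4 of 10 lower and 0 higher after NCS, down to miR-23b* at -2.20. The miR-181 family stood at -0.18 and -0.49, with 2 of 7 lower and 3 higher after NCS, from miR-181a-2* at -1.45 to miR-181b at 2.48. Centred per panel, 2 were lower and 1 higher after NCS, with a median of 0.34, and after neighbour subtraction 0 were lower and 1 higher. The damage-linked miRNAs stood at 0.06 and -0.28, from miR-96 at -1.94 to miR-183* at 1.31 in shDDX1 and from miR-100 at -1.87 to miR-101 at 6.72 after NCS. The chromosome 19 cluster stood at 0.15 and -0.31, with 8 of 48 lower and 5 higher in shDDX1, down to miR-516b at -3.11, and after NCS from miR-525-3p at -2.93 to miR-517a at 1.46. Centred per panel, 4 of its assays were lower and 1 higher in shDDX1, with a median of -0.12. Neighbour subtraction gave the same counts and a median of -0.13. The X-linked cluster from miR-506 to miR-514 had 2 of 9 lower and 2 higher in shDDX1, from miR-514 at -1.71 to miR-513a-5p at 3.0, and only 2 quantified after NCS. After NCS the let-7 family stood at -0.33, the miR-30 family at -0.23, from miR-30c-1* at -1.15 to miR-30e* at 3.19, and the 14q32 cluster at 0.04, from miR-496 at -1.70 to miR-376a at 3.59. Of the miRNAs named for these lists, miR-1236, miR-23b* and miR-27b in shDDX1 and miR-1236, miR-181a-2*, miR-29a*, miR-30c-1*, miR-496 and miR-517a after NCS were within 2-fold when centred per panel, and so was miR-183* in shDDX1. After neighbour subtraction miR-16, miR-16-2* and miR-514 in shDDX1 and miR-29b-2* after NCS were within 2-fold too.

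Panel I miRNAs were lower in shDDX1 relative to panel II miRNAs, with a gap between uncentred panel medians of -0.88. The 3 calibrator wells of panel I read 0.678 cycles later in shDDX1 than in shNS, and those of panel II 0.243 cycles earlier (-0.243). With each plate set to its calibrators the gap was 0.035 (95% interval -0.12 to 0.19), as a plate-to-plate shift would give. The 7 assays present on both panels did not all show a shift of that size. Their uncentred panel I minus panel II differences were -0.17 for miR-103, -0.52 for miR-191, -0.91 for miR-423-5p and 0.81 for U6. They were 0.019 for SNORD38B, -0.42 for SNORD49A and -0.34 for the spike-in UniSp6. Centring each panel raised the SD from these assays from 0.38 to 0.57, so a plate-to-plate shift is not settled. As a test of a shared change at the hairpin, the panel II partner arms of panel I arms at least 2-fold lower were taken. Their median relative log2 ratio was -0.090 (-0.41 to 0.14, 51 pairs), or -0.0028 over the 37 pairs from hairpins with exactly 2 assays. The test could be read in either way. Both intervals (-0.61 to 0.45 for the 37 pairs) leave out the panel-centred medians of the panel I arms themselves, -1.41 and -1.49. Those arms were chosen for being lower, which sets their medians in part, so this does not decide against a shared change. Over all 151 pairs the ratios of the arms had a Spearman correlation of only 0.13. Both intervals are also too wide to exclude a smaller shared change.

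Panel I miRNAs were higher after NCS, most in the middle columns. Calibration took the gap between panels from 1.15 to 0.32 (0.13 to 0.58). By the calibrators a plate shift would account for part of it, and how much remains is open. For the 7 assays on both panels, panel I minus panel II differences were 0.0033 for miR-103, 0.22 for miR-191, 2.71 for miR-423-5p and 0.54 for U6. They were 0.33 for SNORD38B, 0.60 for SNORD49A and -0.84 for UniSp6. Centring each panel raised the SD from these assays from 0.79 to 1.06, so they do not all show 1 common shift. For middle-column miRNAs at least 2-fold higher, mates were taken, meaning the other arm or a neighbour within 10 kb measured outside those wells. The mates had a median calibrated ratio of -0.20 (-0.36 to 0.08, 48 assays), where the assays themselves had 2.01, as an effect of well position would give. Those assays were chosen for being higher, which sets the 2.01 in part. Several share the same mates, such as miR-200a, miR-200b and miR-429, so the interval may be too narrow. An effect of position is therefore not settled. Partner arms on panel II had a median of 0.044 (-0.14 to 0.29, 31 pairs), or 0.038 (-0.25 to 0.29) over 26 pairs from hairpins with exactly 2 assays. Both intervals end below the panel-centred medians of the panel I arms themselves, 1.15 and 1.08. Those arms were chosen for being at least 2-fold higher, which sets their medians in part. Over all 96 pairs the ratios of the arms had a Spearman correlation of only 0.22. A change at the hairpin therefore stays open. In the middle columns of panel I, the median Ct difference from shNS exceeded that in the outer columns by 0.917 cycles in untreated cells, against -0.289 in NCS-treated cells.

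miRNAs lower in shDDX1 tended to be those higher after NCS. After the median of neighbouring wells was taken off, the Spearman correlation on panel I was -0.425 (-0.53 to -0.31) beside -0.524 before, which argues against a smooth position effect as the whole cause. An effect limited to single wells is not tested by this. If miRNAs that depend on DDX1 were those induced by damage, panel II should show the relation too. Its correlation was -0.132 (-0.26 to 0.012). That interval leaves out -0.524, so a relation as strong as on panel I was not seen there. For a weaker one the value is too imprecise to decide. A biological link therefore stays open as a hypothesis.

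The authors' deposited tables differ from the Ct table for miRNAs of the family the study followed. In the authors' deposited normalized table miR-429 in shNS and shDDX1, miR-200c in shDDX1 and miR-200b* in shDDX1 were shifted 2 cycles further than other wells of their panel. The folds given next from Ct values are uncentred, like the authors' own. The miR-200c fold in shDDX1 is 0.489 in the authors' deposited fold table, 1.39 from their normalized values and 0.347 from the Ct values. The miR-21 fold is 0.967 in the authors' deposited fold table and 0.671 from both sets of Ct values. After NCS, the miR-200c fold is 2 in the authors' deposited fold table, 1.3 from their normalized values and 4.96 from the Ct values, where the centred value is 2.98. These miRNAs were singled out after their values were seen.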
